A study of Homo sapiens with 4 samples.

How the data were processed

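Total RNA was sequenced from H929 multiple myeloma cells transduced with a non-silencing shRNA (2 libraries) or an ILF2 shRNA (2 libraries). Per the labels' protocols, RNA was purified on silica columns, ribosomal RNA was depleted, and strand-specific libraries were read as pairs on an Illumina HiSeq. Groups and replicate numbers were taken from the sample titles, and all 4 libraries entered every main test. The library names in the file headers leave open whether both ILF2 shRNA libraries carry the same hairpin, and they were treated as 1 group. The values are raw counts of fragments per gene, made by the authors with featureCounts (Subread 1.4.6-p2) per the file headers. The headers record paired fragments, strand setting 2 (the reverse strand, which fits a kit that marks strand in this way), exons summed by gene and the Ensembl annotation of GRCh37. No option for fragments with several mapping places or several genes is recorded, so these are taken to be left out, as in that program's defaults. This lowers counts of genes with near-identical copies and of overlapping genes on the same strand. Per the submitters' processing notes, STAR 2.3.0 and SAMtools 0.1.19 were also used. The submitters' design text names Tophat2 instead for alignment, and the counts are taken to come from STAR, as the processing notes list it and the alignment names in the file headers end as STAR's do by default.

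The files hold 63677 genes, of which 55665 were matched to a symbol by Ensembl gene ID in GENCODE's GRCh37 annotation and 382 by position on the same strand with a reciprocal overlap of at least 0.9. The remaining 7630 were kept under their IDs. They took 3.41% to 4.08% of fragments in the libraries. No rows without a gene were present, and 32842 genes had a count in any library.

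Counts were compared in edgeR 4.0.16 (R 4.3.3) with TMM normalisation, the filterByExpr filter with its minimum count of 10, robust dispersion estimates and the two-sided quasi-likelihood test, with group as the only term and Benjamini-Hochberg adjustment over the 19142 genes kept. A gene was called at an adjusted p under 0.05. CPM values are counts scaled by the TMM-adjusted library size, and SE of a log2 fold change was obtained from the F statistic. TMM factors ran from 0.970 to 1.02, and the biological coefficient of variation was 5.38%. Counting error adds to this, most of all in genes of a few CPM or less. With 2 libraries per group the fit has 2 residual degrees of freedom and leans on the spread shared across genes.

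Before the data were examined, 32 gene lists were fixed from general knowledge, and 30 of them had at least 5 tested members. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01 with adjustment over the lists, again with the correlation estimated per list, and with fry, which asks whether a list moves on balance in one direction. With the correlation estimated, camera uses the 2 residual degrees of freedom of the fit, so its p can rise without a higher correlation. Some genes stand in more than 1 list. The genes named were also chosen by a fixed rule. It takes ILF2. It takes the 12 largest rises and 12 largest falls among called genes with an edgeR average of at least 1 log2 CPM, a symbol that is not clone-based or a pseudogene's, and groups that do not overlap. It takes up to 4 members of each described list with the smallest adjusted p past 0.05, or the 2 most abundant where none passed. Genes outside that rule are marked as such where they are named, and some genes under it are not reported here.

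Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper-quartile factors in edgeR, no filter, a filter of 1 CPM in 2 libraries, mitochondrial and abundant small RNAs left out, replicate number as a block, a test against an absolute log2 fold change of 0.5 (glmTreat), and each library left out in turn. Added after seeing the data were a crossed pairing, a correction for GC content and exon length (smooth trends per library from mgcv 1.9.3, with a value for 100% of tested genes), the analysis without chromosome 5, the lists without ILF2, and all tests by chromosome, chromosome arm and gene family. Bootstrap intervals are at 95% over 10000 draws of genes. They hold the libraries fixed and treat genes as independent, so they leave out the spread between libraries.

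The procedure was tested on simulated counts of the 19142 tested genes with the means and library sizes of this comparison. Of these, 18750 passed the filter again. At each of 4 sizes 50 genes were changed, all drawn from genes with a mean of at least 1 CPM. The procedure recovered 88% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 1.5 or 2. Of 203 calls, 9 were unchanged genes. Recovery of genes under 1 CPM was not tested. A simulated list of 40 genes moved by 0.3 gave p = 7.4e-20 by camera at the preset and p = 0.0327 with an estimated correlation, and an unmoved list gave p = 0.595 in both. The genes were simulated as independent, so this cannot show how the preset behaves for lists whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.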

Results

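Gene expression was measured by RNA sequencing in H929 cells, an established human multiple myeloma cell line derived from malignant plasma cells. The cells carried either a non-silencing short hairpin RNA (shRNA) or an shRNA against ILF2, which encodes a protein that acts in complexes bound to double-stranded RNA. Each group held 2 libraries of total RNA from which ribosomal RNA had been removed. The non-silencing libraries held 72977082 and 71389341 counted fragments, and the ILF2 shRNA libraries held 63459322 and 71359863. Between 27595 and 28122 genes had at least 1 fragment in a library. The 5 most abundant features, among them the 7SL RNA gene RN7SL2 and the 7SK RNA gene RN7SK, took 10.2% and 10.5% of fragments in the non-silencing libraries. They took 10.3% in ILF2 shRNA replicate 1 and 12.3% in ILF2 shRNA replicate 2. Mitochondrial genes took 0.351% and 0.307% of fragments in the non-silencing libraries and 0.516% and 0.463% in the ILF2 shRNA libraries. Replicates of a group differed by more than counting noise, with a chi-square per gene of 9.17 between the non-silencing libraries and 18.3 between the ILF2 shRNA libraries, more than copies of one library would. This value is a mean over genes scaled by library totals only, and the most abundant features weigh heavily in it. Between libraries of different groups it was 37.6 to 53.3. The replicates are described by the submitters as independent, but whether they came from separate transductions is not given in the sources used here, and p-values measure only the spread between these samples.

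ILF2 was examined first, since its level checks the labels. ILF2 (ENSG00000143621, GRCh37 chromosome 1, 153634512 to 153643524, minus strand) was counted over all of its exons. Its count was 53115 and 52851 fragments in the non-silencing libraries and 6821 and 7911 in the ILF2 shRNA libraries. With library size taken into account this was 725 ± 11.6 normalised counts (CPM; SD, n = 2) against 111 ± 5.13 CPM (SD, n = 2). The log2 fold change was -2.71 (SE 0.07; edgeR adjusted p = 9.2e-39), so 15.3% of the non-silencing level remained.

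**Figure D1:**
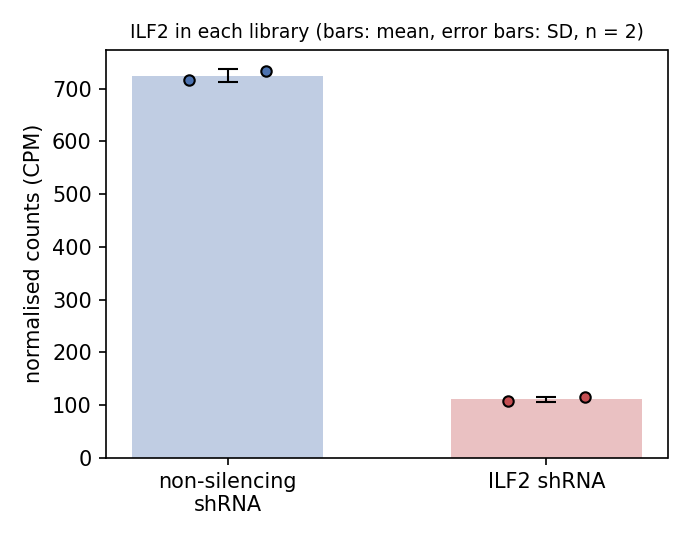
Normalised counts (CPM, vertical axis from 0) of ILF2 in non-silencing and ILF2 shRNA libraries; points are single libraries, bars are means and error bars are SD (n = 2). ILF2 averaged 725 CPM in the non-silencing and 111 CPM in the ILF2 shRNA libraries.

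ILF2 belongs to a list of 16 genes for proteins that bind double-stranded RNA or process small RNAs, of which 4 rose and 3 fell, or 2 and 1 without non-silencing replicate 2. ZFR, whose product shares a domain with the ILF2 protein, rose by a log2 fold change of 0.49 (SE 0.07; edgeR adjusted p = 5.2e-08). It lies on chromosome 5, whose tested genes had a median log2 fold change of 0.15. The RNA helicase gene DHX9 fell, with a log2 fold change of -0.27 and an adjusted p of 0.0015 (edgeR), a call that ended without non-silencing replicate 2 (adjusted p = 0.18). When adjusted over the list alone, 4 rose and 4 fell. The whole list was shifted down by limma's camera test (adjusted p = 0.0296; adjusted p = 0.321 with an estimated correlation), although its median log2 fold change was -0.01 (-0.04 without non-silencing replicate 1, 0.02 without non-silencing replicate 2, 0.03 without ILF2 shRNA replicate 2 and -0.05 without chromosome 5). Without ILF2 itself the direction of that test turned to up and it no longer passed (adjusted p = 0.447), nor did it without ILF2 shRNA replicate 1 (adjusted p = 0.0614).

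The comparison of ILF2 shRNA with non-silencing shRNA asks which transcripts differ in myeloma cells in which ILF2 is reduced. Effects of the hairpin on other genes and differences between the transduced populations cannot be told apart from ILF2 loss in this design. Of 19142 genes tested, 1960 were higher and 1925 lower with ILF2 shRNA (edgeR's quasi-likelihood test, adjusted p under 0.05), or 20.3% of genes. DESeq2 called 1363 higher and 1261 lower, and after the GC and length correction 2849 were higher and 2951 lower. Most differences were small: the median size of a called change was 0.40 on the log2 scale, and 224 genes rose and 224 fell by at least 1 (172 and 138 without non-silencing replicate 1). In 99.9% of called genes both libraries of a group lay above both of the other, as they did in 56.5% of all tested genes, where chance gives 33.3%. Protein-coding genes made up 1626 of the higher and 1633 of the lower genes, or 876 and 912 without non-silencing replicate 1 and 847 and 921 without replicate 2. Of 2481 long non-coding RNA genes tested, 6.93% were higher and 5.72% lower. These shares were 3.65% and 2.52% without non-silencing replicate 1, 3.77% and 2.76% without replicate 2, and 4.49% and 3.01% without ILF2 shRNA replicate 2. The counts fell to 1070 higher and 1073 lower without non-silencing replicate 1, and to 1029 and 1070 without non-silencing replicate 2. Without ILF2 shRNA replicate 2, the library with the largest share in its most abundant features, 1565 were higher and 1489 lower.

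The largest rise among genes of at least 1 log2 CPM was that of RIPOR2 (ENSG00000111913, chromosome 6, 24797601 to 25042238); it went from 0.984 ± 0.116 to 4.19 ± 6.5e-05 CPM (SD, n = 2), a log2 fold change of 2.09 (SE 0.16; edgeR adjusted p = 8.2e-16). SELENOP, which encodes the secreted selenium carrier selenoprotein P, rose by 1.81, and the transcription factor gene GRHL3 by 1.73. TLR7, an endosomal sensor of single-stranded RNA, rose from 4.32 ± 0.172 to 14.2 ± 1.04 CPM (SD, n = 2), a log2 fold change of 1.71 (SE 0.10; edgeR adjusted p = 3.4e-20). ARHGEF28 rose by 1.60, CPED1 by 1.57 and the WNT ligand gene WNT5B by 1.51. The interleukin receptor gene IL23R and the adhesion G protein-coupled receptor gene ADGRG6 each rose by 1.49. The splicing regulator gene MBNL2 rose by 1.37, the sugar transporter gene SLC2A12 by 1.33 and IRAG2 by 1.30. SELENOP and ARHGEF28 lie on chromosome 5.

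After ILF2 itself, the largest fall was that of KIAA1755 (ENSG00000149633, chromosome 20, 36838890 to 36889174), from 11.1 ± 0.0144 to 2.64 ± 0.133 CPM (SD, n = 2), a log2 fold change of -2.08 (SE 0.11; edgeR adjusted p = 1.0e-21). The growth factor genes HBEGF and PDGFB had log2 fold changes of -1.89 and -1.66, and ADM, which encodes the vasodilator peptide adrenomedullin, had one of -1.61. PDGFB went from 21.8 ± 1.34 to 6.87 ± 0.295 CPM (SD, n = 2; edgeR adjusted p = 2.0e-21). The value was -1.75 for MX2, an interferon-induced restriction factor gene, and -1.59 for CIITA, the master regulator of major histocompatibility complex class II genes. It was -1.45 for the RNA-binding protein gene IGF2BP1, -1.35 for MILR1, -1.34 for the syntrophin gene SNTB1 and -1.24 for FLRT3. PTP4A3, a protein tyrosine phosphatase gene, was the most abundant of these after ILF2. It dropped from 58.3 ± 2.31 to 24.3 ± 1.28 CPM (SD, n = 2), a log2 fold change of -1.26 (SE 0.08; edgeR adjusted p = 6.4e-20). The calls of all 24 of these genes held in each alternative setting that tested them.

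**Figure D2:**
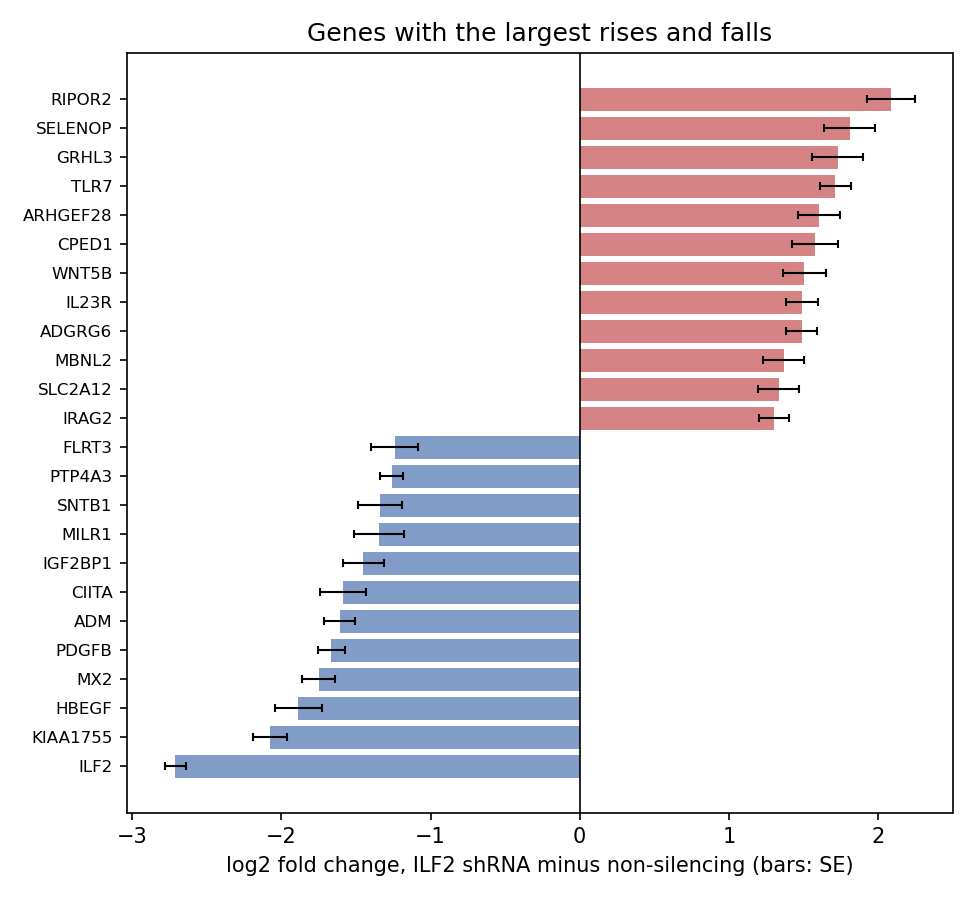
Log2 fold change (ILF2 shRNA minus non-silencing, horizontal axis) of the 12 genes with the largest rises (red) and the 12 with the largest falls (blue) under the rule for named genes; error bars are SE. Values run from -2.71 for ILF2 to 2.09 for RIPOR2.

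Genes of the cell cycle were lower with ILF2 shRNA. Of 47 genes for DNA replication and S phase, 36 fell and 0 rose by edgeR, with a median log2 fold change of -0.27. The falls numbered 21 without non-silencing replicate 1 and 17 without non-silencing replicate 2. At an unadjusted p under 0.05, 40 were lower and 0 higher, and DESeq2 called 36 and 0. E2F2, a transcription factor gene of the G1 to S transition, went from 358 ± 0.273 to 250 ± 12.7 CPM (SD, n = 2), a log2 fold change of -0.52 (SE 0.07; edgeR adjusted p = 1.2e-08). DSCC1, which encodes a cohesion factor at the replication fork, had a log2 fold change of -0.55, the histone chaperone gene ASF1B -0.48 and the replication initiation gene MCM10 -0.41. Of 44 genes for mitosis and G2/M, 31 fell and 0 rose by edgeR, with a median of -0.29. Of these genes 16 fell without non-silencing replicate 2, and 1 rose without ILF2 shRNA replicate 2 or after the GC and length correction. At an unadjusted p under 0.05, 35 were lower and 1 higher, and DESeq2 called 31 and 0. Among them ANLN, which encodes the cytokinesis protein anillin, had a log2 fold change of -0.52 (edgeR adjusted p = 5.5e-08), the transcription factor gene MYBL2 -0.47, the spindle gene ASPM -0.48 and the mitotic kinesin gene KIF11 -0.41. The calls adjusted over the list alone were 40 falls among replication genes, and 35 falls and 1 rise among mitosis genes. Both lists were shifted down by limma's camera test, with adjusted p = 3.1e-17 for replication and 2.7e-15 for mitosis. With the correlation estimated, in a camera test with 2 residual degrees of freedom, these became adjusted p = 0.266 and adjusted p = 0.316. The estimated correlation was 0.0019 for replication and 0.051 for mitosis, against the preset of 0.01. A higher correlation therefore cannot account for the change in the replication list.

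Histone genes that are transcribed in S phase fell together. Of 29 tested, 28 fell and 0 rose, with a median log2 fold change of -0.44 (limma's camera adjusted p = 2.9e-33, and adjusted p = 0.321 with an estimated correlation). The correlation estimated within this list was 0.592, far above the preset of 0.01, so the p at the preset overstates the evidence. By fry the list did not pass (limma's fry adjusted p = 0.0542). The counts were the same in edgeR at an unadjusted p under 0.05, in DESeq2, and adjusted over the list alone. H3C1 had a log2 fold change of -0.72 (SE 0.08; edgeR adjusted p = 7.0e-11). H3C7 and H2AC4 each had a log2 fold change of -0.59, and the linker histone gene H1-3 had one of -0.55. Histone genes of one type are near-identical in their coding sequence, and the authors' counting is taken to leave out fragments that map to several places, so the level of each single histone gene is uncertain. Their transcripts lack poly(A) tails and were measured here because the libraries were made from total RNA. The share of mitochondrial fragments was higher in the same libraries in which these 3 lists were lower.

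**Figure D3:**
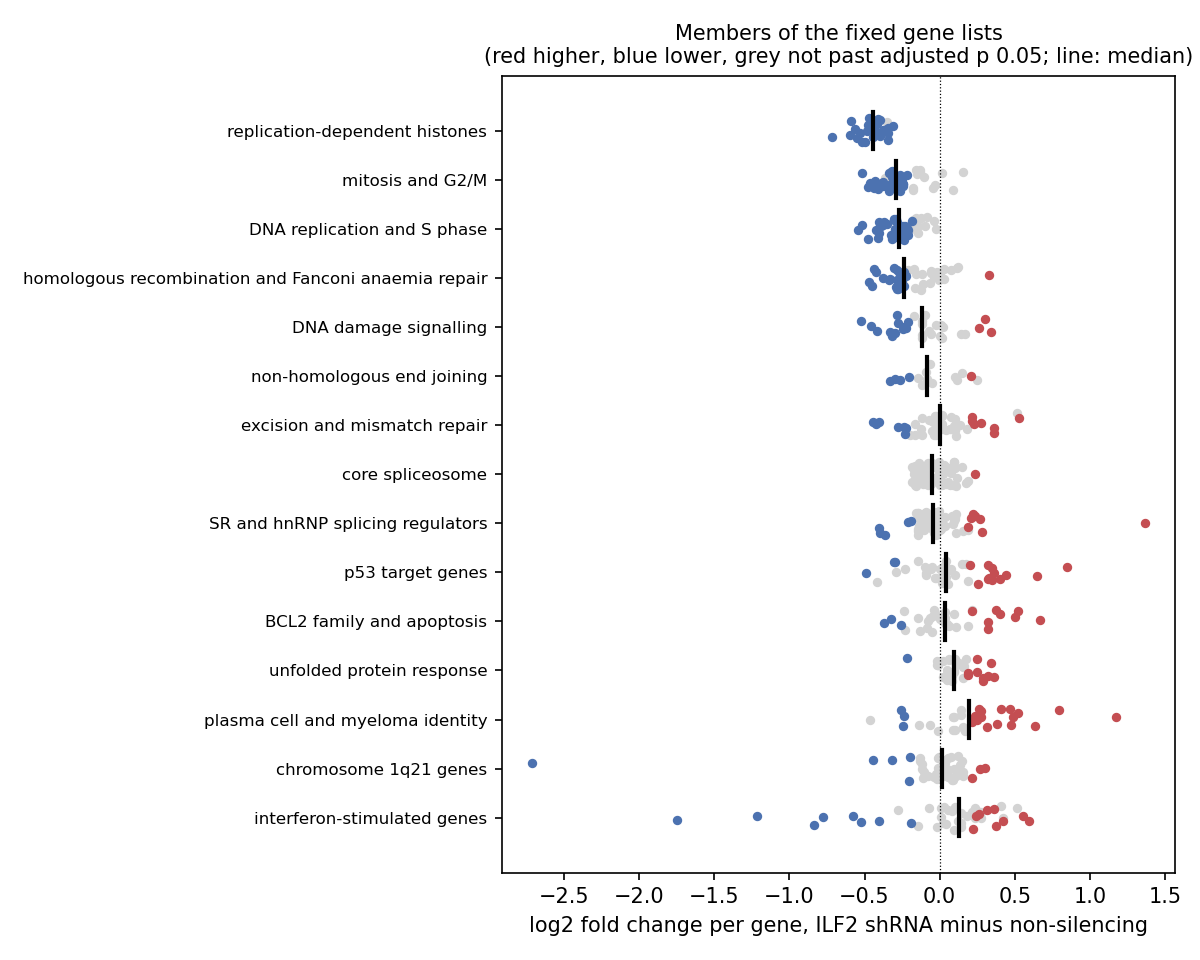
Log2 fold change (ILF2 shRNA minus non-silencing, horizontal axis) of each tested member of 15 of the 32 gene lists; red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not, and black lines are medians. Among the lists drawn, the histone list sits lowest, with a median of -0.44, and the plasma cell list highest, with a median of 0.19.

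Genes for DNA repair were next, since ILF2 has been linked to the DNA damage response. In homologous recombination and the Fanconi anaemia pathway, 22 of 43 genes fell and 1 rose, with a median log2 fold change of -0.24. The falls numbered 7 without non-silencing replicate 2, and 0 genes rose without non-silencing replicate 1 or ILF2 shRNA replicate 1. FANCD2, the gene for a central Fanconi anaemia protein, had 76.8 ± 1.18 CPM in the non-silencing and 55.5 ± 0.762 CPM in the ILF2 shRNA libraries (SD, n = 2), a log2 fold change of -0.47 (SE 0.07; edgeR adjusted p = 6.4e-07). BRCA2 had a log2 fold change of -0.45, FANCL one of -0.44 and XRCC2 one of -0.42. The riser was RAD50, named because it was the only one; it lies on chromosome 5, and with that chromosome left out 21 of 42 genes fell and 0 rose. There were 25 falls and 1 rise adjusted over the list alone. The list was shifted down (limma's camera adjusted p = 1.5e-06, and adjusted p = 0.321 with an estimated correlation) but not by fry (limma's fry adjusted p = 0.0711). Its median lay near the -0.27 of the replication list and the -0.29 of the mitosis list. Whether the fall of these repair genes is separate from the fall of cell cycle genes was not tested.

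Of 30 DNA damage signalling genes, 12 fell and 3 rose (limma's camera adjusted p = 0.0055, and adjusted p = 0.347 with an estimated correlation), and the list did not pass by fry (limma's fry adjusted p = 0.0662). Only 5 fell without non-silencing replicate 2, and 0 rose without non-silencing replicate 1. The smallest adjusted p were those of RNF168, a ubiquitin ligase gene of the double-strand break response (log2 fold change -0.52, edgeR adjusted p = 4.1e-07), the checkpoint kinase gene WEE1 (-0.46) and the histone variant gene H2AX (-0.42). The counts were 12 and 4 adjusted over the list alone. Some genes of this signalling list also stand in the replication or mitosis list, and whether its falls are separate from those was not tested. Non-homologous end joining had 4 falls and 1 rise among 15 genes and was not shifted as a list (limma's camera adjusted p = 0.222). PRKDC, which encodes the catalytic subunit of DNA-dependent protein kinase, was lower by a log2 fold change of -0.33 (SE 0.07; edgeR adjusted p = 9.2e-05), and RIF1 had one of -0.30, a call that ended without non-silencing replicate 2 (adjusted p = 0.17). The end joining counts were again 4 and 1 adjusted over the list alone, but 2 and 0 without either non-silencing library, and 0 rose without ILF2 shRNA replicate 2. Here 2 rose after the GC and length correction, and 0 by DESeq2, with upper-quartile factors or with no low-count filter. Excision and mismatch repair genes went both ways, with 7 of 47 higher and 7 lower, also when adjusted over the list alone (limma's camera adjusted p = 0.904). These became 3 and 3 without non-silencing replicate 1, then 2 and 2 without non-silencing replicate 2, and 4 rose without ILF2 shRNA replicate 1. Only 3 rose by DESeq2, with upper-quartile factors or with no low-count filter. Among them the DNA ligase gene LIG1 (-0.42) fell, and the glycosylase gene NEIL1 rose by 0.53.

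Target genes of the tumour suppressor p53 were shifted up: 12 of 40 rose and 3 fell (limma's camera adjusted p = 0.0181, and adjusted p = 0.321 with an estimated correlation), with a median log2 fold change of 0.04. That median was 0.09 without non-silencing replicate 2 and 0.06 without ILF2 shRNA replicate 2 and by DESeq2; 1 gene fell without non-silencing replicate 1, and 5 after the GC and length correction. CCNG1, which encodes cyclin G1, went from 306 ± 19.4 to 552 ± 21.7 CPM (SD, n = 2), a log2 fold change of 0.85 (SE 0.07; edgeR adjusted p = 2.2e-15); it lies on chromosome 5. TP53INP1 rose by 0.65, the antiproliferative gene BTG2 by 0.44 and the death receptor gene TNFRSF10B by 0.32. There were 12 rises and 4 falls adjusted over the list alone. Without chromosome 5, 11 of 37 rose and 2 fell. Genes of the BCL2 family and apoptosis had 8 rises and 3 falls among 33, or 8 and 4 adjusted over the list alone, and were not shifted as a list (limma's camera adjusted p = 0.407). There were 3 rises and 1 fall without non-silencing replicate 2, and 1 fall without non-silencing replicate 1. DESeq2 called 5 rises, and 6 fell after the GC and length correction. The proapoptotic genes BCL2L11, which encodes BIM, and BIK rose by 0.50 and 0.67 (edgeR adjusted p = 1.7e-06 and 8.9e-06). APAF1, the apoptosome scaffold gene, had a log2 fold change of -0.37, a call that ended without non-silencing replicate 2 (adjusted p = 0.10).

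Of 64 core spliceosome genes, 1 rose and 0 fell by edgeR and by DESeq2, and 3 were higher and 8 lower at an unadjusted p under 0.05. After the GC and length correction 5 rose and 15 fell, and 1 fell with no low-count filter or under the stricter filter. Their log2 fold changes ran from -0.19 to 0.24, and the list was not shifted (limma's camera adjusted p = 0.408). The riser was SF3B5, with a log2 fold change of 0.24 (edgeR adjusted p = 0.0094), and no gene passed when adjusted over the list alone. Its call ended without either non-silencing library or without ILF2 shRNA replicate 2 (adjusted p = 0.082, 0.25 and 0.17). Rises and falls in this list numbered 0 and 1 without non-silencing replicate 2, 2 and 4 without ILF2 shRNA replicate 1, and 2 and 1 without ILF2 shRNA replicate 2. Of 61 SR and hnRNP genes and other splicing regulators, 7 rose and 5 fell, also when adjusted over the list alone (limma's camera adjusted p = 0.566), but 2 and 3 without either non-silencing library, and 4 rose without ILF2 shRNA replicate 1. In this list 10 rose and 15 fell after the GC and length correction, while 3 rose by DESeq2 and 4 by limma-voom or with upper-quartile factors. MBNL2, from the list of largest rises, was at 1.37, HNRNPDL and SRSF4 each had a log2 fold change of -0.40 (edgeR adjusted p = 9.9e-06 and 1.2e-05) and RBFOX2 one of -0.36. The submitters' design also names differential splicing, which counts per gene cannot show and which was not analysed here.

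Genes of plasma cell and myeloma identity were higher. Of 32 tested, 16 rose and 3 fell (9 and 0 without non-silencing replicate 2, and 0 falls without non-silencing replicate 1), with a median log2 fold change of 0.19 (limma's camera adjusted p = 7.3e-10, and adjusted p = 0.266 with an estimated correlation). FGFR3 (ENSG00000068078, chromosome 4, 1795034 to 1810599), a receptor tyrosine kinase gene that a translocation activates in a subset of myelomas, went from 151 ± 10.8 to 341 ± 6.70 CPM (SD, n = 2), a log2 fold change of 1.18 (SE 0.07; edgeR adjusted p = 7.8e-21). FCRL5, a surface protein gene of the B lineage, rose by 0.79, the elongation factor gene ELL2 by 0.64 and DERL3, of endoplasmic reticulum-associated degradation, by 0.52. The counts were 19 and 3 adjusted over the list alone, and without chromosome 5, where ELL2 lies, 15 of 30 rose and 3 fell. The unfolded protein response list, which covers chaperones and degradation factors of the endoplasmic reticulum, had 9 rises and 1 fall among 34 genes, with a median of 0.10 (limma's camera adjusted p = 0.0019, and adjusted p = 0.321 with an estimated correlation). HERPUD1 rose by 0.32 (edgeR adjusted p = 0.00015) and EDEM2 by 0.34. WFS1 rose by 0.36, a call that ended without non-silencing replicate 2 (adjusted p = 0.075). Adjusted over the list alone, 11 rose and 1 fell. In that list 4 rose without non-silencing replicate 1 and 3 without non-silencing replicate 2, and 0 fell without either or without ILF2 shRNA replicate 2. After the GC and length correction 15 rose.

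ILF2 lies in chromosome band 1q21, which is often gained in myeloma. Of 41 tested genes in the list fixed for that band, 5 fell, ILF2 included, and 3 rose, also when adjusted over the list alone (limma's camera adjusted p = 0.12). Without non-silencing replicate 1, 3 fell, and without non-silencing replicate 2, 2 fell and 0 rose; after the GC and length correction 11 fell and 6 rose. S100A4 had a log2 fold change of -0.44 (edgeR adjusted p = 4.0e-06). The list passed without ILF2 shRNA replicate 2 (adjusted p = 0.031) and after the GC and length correction (adjusted p = 0.0242), but with ILF2 left out its direction turned to up (adjusted p = 0.952). Cholesterol synthesis genes were slightly higher, with 6 of 24 rising and 0 falling by edgeR and DESeq2, 10 higher and 2 lower at an unadjusted p under 0.05, and a median of 0.12 (limma's camera adjusted p = 0.0158, and adjusted p = 0.321 with an estimated correlation), but they did not pass by fry (limma's fry adjusted p = 0.0571). Only 1 rose without non-silencing replicate 1, and 1 fell without ILF2 shRNA replicate 2; after the GC and length correction 12 rose and 1 fell. DHCR7, which encodes the last enzyme of one branch of the pathway, rose by 0.32 (SE 0.07; edgeR adjusted p = 0.00065), and INSIG1 by 0.31, a call that ended without non-silencing replicate 1 (adjusted p = 0.057). The count was 7 rises adjusted over the list alone.

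Interferon-stimulated genes split. Of 44, 9 rose and 8 fell, and the list was not shifted (limma's camera adjusted p = 0.629); adjusted over the list alone, 11 rose and 9 fell. Rises numbered 4 without either non-silencing library, and falls 5 without non-silencing replicate 1. DESeq2 called 5 and 5, and after the GC and length correction 14 rose. MX2 (-1.75), the oligoadenylate synthetase gene OAS3 (-0.78) and PLSCR1 (-0.57) fell, while SAMD9L rose by 0.55 (SE 0.08; edgeR adjusted p = 6.7e-07). The list's median was 0.13 and its mean 0.01. NF-kB target genes had 7 rises and 1 fall among 19, or 8 and 1 adjusted over the list alone, and were not shifted as a list (limma's camera adjusted p = 0.225); 4 rose without non-silencing replicate 1 or by DESeq2, and 1 without non-silencing replicate 2. The fall was that of the adhesion molecule gene ICAM1, with a log2 fold change of -0.55 (SE 0.07; edgeR adjusted p = 2.9e-08). NFKB2 rose by 0.41 and BCL3 by 0.56, and the call of BCL3 ended without non-silencing replicate 2 (adjusted p = 0.12).

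Markers of cell types other than plasma cells moved in both directions. Of 14 T and NK lymphocyte markers 6 could be tested, and 2 rose and 0 fell by edgeR and DESeq2, or 2 and 1 at an unadjusted p under 0.05. CD3E, a subunit gene of the T cell receptor complex, rose from 7.86 ± 0.514 to 16.5 ± 0.683 CPM (SD, n = 2), a log2 fold change of 1.07 (SE 0.09; edgeR adjusted p = 8.2e-14), and GNLY, the gene for the cytotoxic granule protein granulysin, rose by 1.36. That list was shifted up (limma's camera adjusted p = 0.0181, and adjusted p = 0.321 with an estimated correlation), and adjusted over the list alone 2 rose and 1 fell. Its median log2 fold change was only 0.02, and 50% of its tested members were above 0. In the same libraries CD3D, CD3G and CD2 were each counted in at most 4 fragments. Of 8 B lymphocyte genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (limma's camera adjusted p = 0.132). CIITA (-1.59) and FCER2 (-0.61) were the falls, and BLK and CR2 the rises. BLK averaged only 0.0615 CPM in the non-silencing and 0.229 CPM in the ILF2 shRNA libraries. There were 0 rises without either non-silencing library or ILF2 shRNA replicate 1, and 1 without ILF2 shRNA replicate 2. The list passed without non-silencing replicate 2 (adjusted p = 0.0408). Of 5 fibroblast and stroma genes 1 rose (ACTA2, 0.61) and 1 fell (TAGLN, -0.46), and of 7 epithelial and packaging-line genes 2 rose (GAL, 0.70, and KRT18, 0.30) and 2 fell, CLDN7 and CDH1, each under 1 CPM. These counts were the same adjusted over the list alone, and neither list was shifted (limma's camera adjusted p = 0.954 and 0.682). The calls of TAGLN and CLDN7 ended without non-silencing replicate 1 (adjusted p = 0.10 and 0.088) or ILF2 shRNA replicate 1 (adjusted p = 0.12 and 0.059), and that of KRT18 without non-silencing replicate 2 (adjusted p = 0.10). That of ACTA2 ended without either replicate 2 (adjusted p = 0.15 and 0.12), and that of CDH1 without either non-silencing library (adjusted p = 0.27 and 0.083) or ILF2 shRNA replicate 1 (adjusted p = 0.34). The calls of CR2, ACTA2 and TAGLN also ended in DESeq2 (adjusted p = 0.19, 0.078 and 0.099), which gave no adjusted p for BLK, CLDN7, CDH1 or CSF1R. Of 12 monocyte and macrophage markers 2 could be tested, and CSF1R fell from 0.569 ± 0.0789 to 0.309 ± 0.0287 CPM (SD, n = 2; edgeR adjusted p = 0.048), a call that ended in limma-voom (adjusted p = 0.063), with no low-count filter (adjusted p = 0.055) and with each of the 4 libraries left out in turn (adjusted p = 0.090 and 0.33 for the non-silencing and 0.078 and 0.19 for the ILF2 shRNA libraries). No erythroid marker had enough fragments to be tested under the main filter. DESeq2, which was run without that filter, covered 6 and called 0.

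Genes of the cytoplasmic ribosome were slightly higher, with 11 of 77 rising and 0 falling by edgeR, 16 higher and 1 lower at an unadjusted p under 0.05, 12 and 0 by DESeq2, and a median log2 fold change of 0.08 (limma's camera adjusted p = 0.0029, and adjusted p = 0.321 with an estimated correlation). RPL13A rose from 975 ± 4.68 to 1315 ± 82.6 CPM (SD, n = 2), a log2 fold change of 0.43 (edgeR adjusted p = 8.5e-07). Ribosomal protein genes have many processed pseudogenes, so single levels are uncertain. Of the 11, 3 lie on chromosome 5 (RPL37, RPS23 and RPS14, named for their position after the values were seen), and the calls of RPL37 and RPS14 ended without non-silencing replicate 1 (adjusted p = 0.096 and 0.11). Adjusted over the list alone, 9 ribosomal protein genes rose. There were 4 rises and 1 fall without non-silencing replicate 1, 3 rises without non-silencing replicate 2 and 17 without ILF2 shRNA replicate 1. The GC and length correction gave 18 rises and 2 falls, and 1 fell under the stricter filter. Genes for ribosome biogenesis and other MYC targets showed 2 rises and 3 falls among 48, also when adjusted over the list alone (limma's camera adjusted p = 0.0956), and that list passed after the GC and length correction (adjusted p = 0.0297) and by fry (limma's fry adjusted p = 0.0443). In it 1 rose without non-silencing replicate 1 and 0 without non-silencing replicate 2, and 7 fell without ILF2 shRNA replicate 1. The GC and length correction gave 5 rises and 20 falls, and 5 fell by DESeq2, with upper-quartile factors or under the stricter filter. WDR43, a ribosome assembly gene, had a log2 fold change of -0.39 (edgeR adjusted p = 1.4e-05). MYC itself rose by 0.32, a call that ended without non-silencing replicate 2 (adjusted p = 0.11).

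Of 13 mitochondrially encoded mRNAs, a measure of RNA quality as well as of mitochondrial expression, 7 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.28. By DESeq2 5 rose and 0 fell, and at an unadjusted p under 0.05 in edgeR 8 and 0. The list was shifted up (limma's camera adjusted p = 0.00029, and adjusted p = 0.55 with an estimated correlation) but not by fry (limma's fry adjusted p = 0.27). The estimated correlation was 0.896, far above the preset of 0.01, so the p at the preset overstates the evidence. MT-CO2, a subunit gene of cytochrome c oxidase, went from 410 ± 29.8 to 591 ± 39.1 CPM (SD, n = 2), a log2 fold change of 0.53 (SE 0.07; edgeR adjusted p = 1.2e-08). Without ILF2 shRNA replicate 1 the list no longer passed (adjusted p = 0.069), with 4 rises and a median of 0.09. Only 1 rose without non-silencing replicate 2, and 12 rose without ILF2 shRNA replicate 2, where the median was 0.45, while 3 rose after the GC and length correction. Nuclear genes of oxidative phosphorylation had 6 rises and 0 falls among 48, or 5 and 0 adjusted over the list alone, 7 and 0 by DESeq2, and 16 and 1 at an unadjusted p under 0.05. Rises numbered 2 without non-silencing replicate 1, 1 without non-silencing replicate 2 and 10 without ILF2 shRNA replicate 1, and the GC and length correction gave 15 rises and 4 falls, with a median of 0.03. Without that correction their median was 0.07 (limma's camera adjusted p = 0.0433, and adjusted p = 0.321 with an estimated correlation). Of the 6, 4 lie on chromosome 5, among them SDHA (0.31) and COX7C (0.28), whose calls ended without non-silencing replicate 2 and 1 (adjusted p = 0.077 and 0.14). Without that chromosome the list was not shifted (adjusted p = 0.133), nor was it without non-silencing replicate 1 (adjusted p = 0.111) or ILF2 shRNA replicate 1 (adjusted p = 0.0522), under the stricter filter (adjusted p = 0.0867) or after the GC and length correction (adjusted p = 0.0521). Glycolysis and hypoxia genes had 7 rises and 4 falls among 33, or 7 and 5 adjusted over the list alone (limma's camera adjusted p = 0.21), and passed without ILF2 shRNA replicate 2 (adjusted p = 0.0452). Here 3 rose without non-silencing replicate 1 and 2 without non-silencing replicate 2, and 11 fell after the GC and length correction. ADM (-1.61), the circadian repressor gene BHLHE40 (-0.62) and the glucose transporter gene SLC2A1 (-0.47) fell, and MXI1 rose by 0.42.

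Nuclear long non-coding RNAs and snoRNA host genes showed 5 rises and 1 fall among 24, also when adjusted over the list alone (limma's camera adjusted p = 0.0226, and adjusted p = 0.321 with an estimated correlation). MIAT rose from 10.2 ± 0.0151 to 18.3 ± 0.633 CPM (SD, n = 2), a log2 fold change of 0.85 (edgeR adjusted p = 4.6e-11), and DANCR rose by 0.32, a call that ended without non-silencing replicate 1 (adjusted p = 0.053), as did that of the list (adjusted p = 0.09). Rises and falls in it numbered 1 and 0 without non-silencing replicate 1 and 3 and 0 without non-silencing replicate 2, and 0 fell without ILF2 shRNA replicate 2. With the GC and length correction 9 rose and 2 fell. Genes of the ATF4 and amino-acid response had 3 rises and 3 falls among 33, also when adjusted over the list alone (limma's camera adjusted p = 0.566). There was 1 rise without non-silencing replicate 1 or ILF2 shRNA replicate 2, and 0 without non-silencing replicate 2, while 8 fell after the GC and length correction. The folate enzyme gene ALDH1L2 had a log2 fold change of -0.61 (edgeR adjusted p = 2.7e-10) and ATF5 one of -0.40. Heat shock and immediate-early genes had 2 rises and 2 falls among 26, or 2 and 1 adjusted over the list alone (limma's camera adjusted p = 0.879). These were 0 falls without non-silencing replicate 1, 0 rises and 1 fall without non-silencing replicate 2, and 1 rise and 5 falls without ILF2 shRNA replicate 1. The GC and length correction gave 4 rises and 8 falls, DESeq2 gave 1 rise, and 1 fell with chromosome 5 left out. IER2 had a log2 fold change of -0.33, a call that ended without non-silencing replicate 1 (adjusted p = 0.12), and JUN one of 0.30, a call that ended without non-silencing replicate 2 (adjusted p = 0.53) or ILF2 shRNA replicate 1 (adjusted p = 0.054) and in DESeq2 (adjusted p = 0.071).

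When called genes were counted by chromosome, a step added after the data were seen, chromosome 5 stood apart. Of its 900 tested genes 267, or 29.7%, were higher and 30 lower, against 9.26% higher over the other nuclear chromosomes. These shares were 14.6% against 4.88% without non-silencing replicate 1 (138 higher, 18 lower) and 16.8% against 4.56% without non-silencing replicate 2 (159 higher, 18 lower). Without ILF2 shRNA replicate 2, 17 were lower. The median log2 fold change on chromosome 5 was 0.15 (95% bootstrap interval over genes, not libraries, 0.13 to 0.17), and medians on the others ran from -0.04 to 0.01. The shift passed limma's camera test (adjusted p = 5.6e-08 over the chromosomes; adjusted p = 0.982 with an estimated correlation). It was seen in both ILF2 shRNA libraries, with medians of 0.18 and 0.13 against the non-silencing mean, while the non-silencing libraries differed from each other by a median of 0.04. With chromosome 5 left out, 1742 genes were higher and 1834 lower, and 14 of the 15 shifted lists still passed, the exception being nuclear oxidative phosphorylation.

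**Figure D4:**
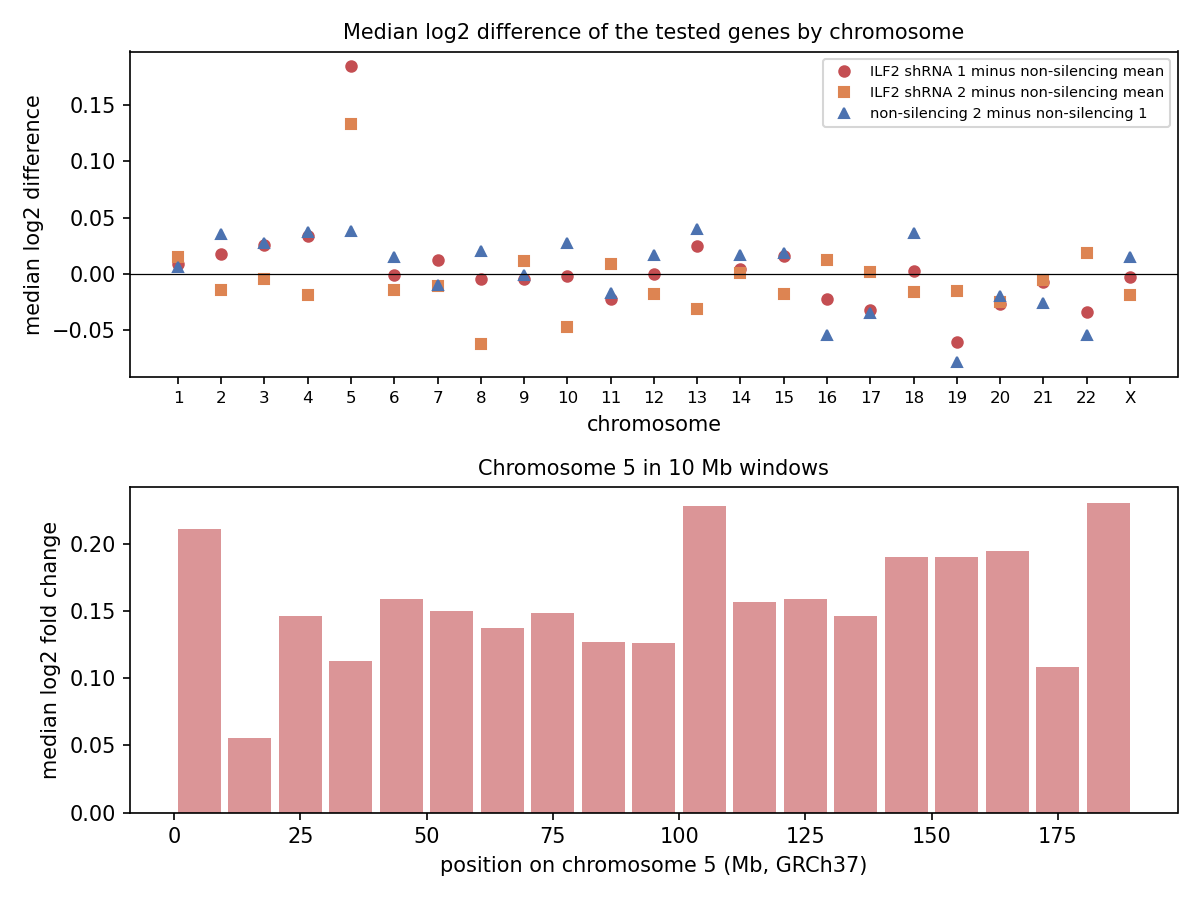
Upper panel: median log2 difference (vertical axis) of the tested genes on each nuclear chromosome, for each ILF2 shRNA library against the non-silencing mean (circles and squares) and between the non-silencing libraries (triangles). Lower panel: median log2 fold change of chromosome 5 genes in 10 Mb windows along GRCh37, with all 19 windows above 0.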

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

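The GC and length correction, the crossed pairing, and the analyses without chromosome 5 or without ILF2 were chosen after seeing the data; the other settings were planned. The ILF2 log2 fold change stayed between -2.76 and -2.66 and past the threshold in every setting run. No called gene changed sign in any setting that gave it a value, whether or not it was called there. This was largely fixed in advance and is no separate support. Every setting reuses the same libraries, and in 99.9% of called genes both libraries of a group lay above both of the other. Against 1960 higher and 1925 lower genes, DESeq2 called 1363 higher and 1261 lower, and the cause was not tested. The test against a log2 fold change of 0.5 called 155 higher and 126 lower, as a stricter hypothesis must call fewer. The GC and length correction called 2849 higher and 2951 lower, and the cause was not tested. In a fit without a non-silencing library, the spread comes from the ILF2 shRNA pair alone. The chi-square per gene of that pair was 18.3, against 9.17 for the non-silencing pair. A call that ended in such a fit therefore need not hinge on the library left out. Leaving out each library in turn gave 1029 to 1899 higher and 1070 to 1822 lower genes from fewer samples, where the lone library of a group is assumed to vary like the other group; the low ends came from leaving out a non-silencing library (1070 and 1073 without replicate 1, 1029 and 1070 without replicate 2). Of 15 shifted lists, 0 passed limma's camera with the correlation estimated per list (smallest adjusted p = 0.266; 3 at an unadjusted p under 0.05), a test with 2 residual degrees of freedom. The estimated correlation was 0.0019 for replication and -0.019 for plasma cell genes, below the preset of 0.01. In those lists the higher p reflects the few degrees of freedom. It was 0.592 for histones and 0.896 for mitochondrial mRNAs, far above the preset. Of the 15, fry kept 10, losing homologous recombination, DNA damage signalling, histones, cholesterol synthesis and mitochondrial mRNAs, and it added the MYC list, 11 in all. Leaving out each library gave 12 to 17 lists. Under the stricter filter 13 passed: oxidative phosphorylation did not (adjusted p = 0.0867), and the T and NK list had too few tested members there. Of 129 genes under the naming rule besides ILF2, all called, 84 kept their call in every setting other than glmTreat, and 30 passed glmTreat.

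With replicate number as a term (replicate block), 1291 genes were higher and 1297 lower, and 13 lists passed, without oxidative phosphorylation and the double-stranded RNA list; the cause was not tested. The numbers are shared only as numbers: deviations of same-numbered libraries correlated at -0.02 over all tested genes and -0.30 over genes of at least 1 log2 CPM. Pairing them crosswise gave 2871 higher and 2857 lower genes and 16 lists.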

Other observations

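The tests in this part were all chosen after the results were seen. Gene families, grouped by the letters that open their symbols, were compared with all other genes where at least 12 members were tested. Of 147 families 2 passed limma's camera test. These 2 share members with the histone and mitochondrial mRNA lists described above, in the same libraries, so they add no separate support. The symbols made of H and a digit, nearly all histone genes, had 45 falls and 1 rise (0 rises without either non-silencing library or ILF2 shRNA replicate 2) among 61 members (adjusted p = 5.3e-29, and adjusted p = 0.951 with an estimated correlation), with a median log2 fold change of -0.40. The MT symbols, mitochondrial genes but for 3 metallothionein genes, had 8 rises and 0 falls among 32 (adjusted p = 0.0102, and adjusted p = 0.951 with an estimated correlation). The MT rises numbered 3 without non-silencing replicate 2 and 5 without ILF2 shRNA replicate 1, and 1 gene fell without ILF2 shRNA replicate 2. Small nuclear RNA genes had 14 rises (4 without non-silencing replicate 1, 9 without ILF2 shRNA replicate 2) and 0 falls among 71 but did not pass as a class (limma's camera adjusted p = 0.129), and many of them are near-identical copies whose counts are uncertain.

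Genes of chromosome 5 were higher with ILF2 shRNA, by a median log2 fold change of 0.15 or 1.11-fold. A few strongly changed genes would leave the share of risers ordinary, but 71.2% of chromosome 5 genes had a log2 fold change above 0, against 43.9% to 51.4% on the other nuclear chromosomes, and a trend with GC content or gene length is argued against by the corrected median of 0.14, above the -0.04 to 0.001 of the others. A gain of only part of the chromosome is argued against by the medians of 0.13 on the short and 0.15 on the long arm, both above the 0.03 of the highest other arm. A different dose of the whole chromosome between the transduced populations, such as a subclone with another copy, is consistent with the lowest of the 4 medians by arm and library, 0.11, since no other arm exceeded 0.06 in ILF2 shRNA replicate 1 or 0.02 in replicate 2. This is a hypothesis: DNA copy number was not measured, both ILF2 shRNA libraries may come from the same population, and an effect of ILF2 loss on these genes stays open and untested.

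Replication and mitosis genes were lower together. A trend with GC content or gene length is argued against, since after that correction the median over both lists was -0.29 against no lower than -0.08 in 10000 random lists matched on abundance. Cells held in mitosis would keep mitotic transcripts up, whereas the mitosis median was -0.29 (95% bootstrap interval over genes, not libraries, -0.33 to -0.25). A smaller share of cycling cells is consistent with the like falls of both lists, whose medians differed by 0.0233 (95% bootstrap interval -0.04 to 0.08), as a hypothesis. Lower transcript levels per cycling cell would look the same in these data, and whether ILF2 loss acts on these genes directly was not tested. The S-phase histone list fell further, with a median of -0.44 and no tested member above -0.31. The like falls thus hold for the replication and mitosis lists and not for all cycle genes, and why was not tested.

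CD3E and GNLY were higher with ILF2 shRNA. T lymphocytes mixed into the cultures are argued against, since CD3D, CD3G and CD2 together rose by 0.0266 CPM while CD3E rose by 8.69 CPM. NK lymphocytes are argued against less firmly. NKG7, GZMB and KLRD1 together changed by -0.0946 CPM while GNLY rose by 1.41 CPM, but this sum nets opposite moves. NKG7 alone rose by 0.180 CPM, while GZMB changed by -0.255 CPM and KLRD1 by -0.0195 CPM. Higher RNA levels of both genes in the myeloma cells themselves may remain as the explanation, as a hypothesis that was not tested further.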
